A study of Mus musculus with 2 samples.

How the data were processed

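Long reads from 2 heart libraries of 1 group were analysed. The authors deposited, for each library, whole-number read counts per transcript model and an annotation of all models; the counts were not normalized, and every listed model was found to have at least 1 read. Per the deposited text descriptions, coordinates are in mm10 and known models come from the GENCODE M21 annotation, while the source column of the annotation names TALON for new models. The aligner, the read filters and the versions are not given in the sources used here. The labels also name SIRV spike-ins, which were not analysed here. The reference annotation used for positions and gene types was the same GENCODE release. Mapping and model building by the authors decide which gene a read is given to, so genes with near-identical copies or overlapping names have uncertain counts.

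New models carry identifiers of their own library. Spliced models were therefore matched between libraries by chromosome, strand and intron chain, and single-exon new models by overlap on a strand. Gene counts were the sum of all models of an annotated gene, and CPM was computed per 1e6 mouse reads, new genes included and spike-ins left out. Log2 ratios used a pseudocount of 1 CPM.

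With 2 libraries of 1 group no test between conditions was possible. Genes with at least 10 reads in both libraries together were compared by an exact two-sided binomial test against the libraries' share of mouse reads, with Benjamini-Hochberg adjustment and a threshold of 0.05. edgeR 4.0.16 in R 4.3.3 gave the common dispersion with an intercept only and TMM factors (1.02 and 0.979), and DESeq2 1.42.0 gave size factors as an alternative. The labels give the libraries as separate replicates. The summed chi-square between them was 2.58 per gene, so they are not the same reads deposited again. The synthetic ERCC spike-ins gave 4.44 per spike-in. This measure therefore cannot show whether the counts came from separate libraries, animals or preparations. Shares have 95% Clopper-Pearson intervals and were compared with Fisher's exact test (scipy 1.17.1). Isoform shares were compared by Fisher's exact test of the transcript with the most reads against all others, in genes with at least 20 reads in each library. The median log2 ratio of each list was set against 10000 random lists matched on mean CPM in 20 bins. Later lists were also matched on transcript length, with coarser CPM bins and only genes that had reads on known transcripts. Inequality of marker ratios was set against 100000 lists drawn from a negative binomial distribution with 1 common factor and the edgeR common dispersion. Near-identical copies were found with blastn 2.17.0 on the annotated transcripts, at 90% identity or more over at least 50% of the shorter sequence in 1 alignment. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

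The rule for named genes was fixed before the data were examined. It took the 20 genes with the highest mean CPM, the 5 largest and 5 smallest ratios among called genes with a mean of at least 50 CPM, up to 6 members of each list with the highest mean CPM, cell type list members without reads, up to 15 cardiac isoform genes with at least 50 reads in each library, 10 new spliced transcripts and 5 new genes with the most reads in the lower library, and the 5 isoform differences with the smallest adjusted p. Some items that the rule names are not reported here. The listed names Ctgf and Klotho match no symbol of the reference.

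The tests were tested on simulated data for replicate 2 against replicate 1. Among 8477 simulated genes the binomial test called 86.0% of genes raised 4-fold, 38.0% raised 2-fold, 66.7% lowered 4-fold, 35.6% lowered 2-fold and 0.0724% of unchanged genes. The median lay outside the central 95% in 4.5% of unshifted and 100% of simulated lists shifted by 1 log2 unit. These lists held 15 random genes each. Smaller shifts, other list sizes and genes that vary together were not simulated, so neither rate is known for the lists reported. Among 3940 genes the isoform test called 30.5% of 200 genes whose top share was moved by 20 percentage points and 0.0535% of unchanged genes. The counts simulated for the binomial and isoform tests held counting noise only. Their rates of calls among unchanged genes therefore do not carry over to these libraries, which can spread more. Alternatives covered scaling, count minimums, the reads counted, thinning of the deeper library and leaving out each replicate.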

Results

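Long-read RNA sequencing was carried out on heart tissue of male B6CASTF1/J mice, the first-generation cross of the C57BL/6J and CAST/EiJ strains, aged 18 to 20 months. The series holds 1 group with 2 libraries, each made from 2 µg of RNA and labelled as separate biological replicates that carry the same donor identifier. There was therefore no contrast between conditions, and the comparisons concern the composition of the heart transcriptome and the spread between these 2 libraries. Every test compares these libraries and not conditions. The p-values of the binomial and Fisher tests treat reads as independent and set a difference against counting error only, and the spread between these samples may be technical. Replicate 1 held 699529 reads and replicate 2 held 1019974 reads, of which 688861 and 1003999 were assigned to mouse models and the others to ERCC spike-ins. A count of 0 allows up to 4.36 CPM (mouse reads scaled to counts per 1e6) in replicate 1 and 2.99 CPM in replicate 2. Intervals are 95% Clopper-Pearson intervals and cover counting error only.

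The first question was which genes these hearts expressed most. Genes of energy metabolism and contraction led both libraries, and the 20 highest genes took 17.4% of mouse reads in replicate 1 and 17.9% in replicate 2. Slc25a4, the adenine nucleotide carrier of the inner mitochondrial membrane, was highest at 23849 ± 610 CPM (SD, n = 2) and lies on chromosome 8 from 46206797 to 46211284 (mm10). It was followed by Myh6, the alpha myosin heavy chain (chromosome 14, 54941921 to 54966927), at 16201 ± 1124 CPM, by Fabp3, the heart fatty acid binding protein, at 12069 ± 2135 CPM, and by the ATP synthase subunit Atp5b at 12065 ± 14.9 CPM. Tpm1 (alpha tropomyosin) stood at 11366 ± 728 CPM, Cox4i1 at 11068 ± 1216 CPM and Pln (phospholamban, the regulator of the sarcoplasmic calcium pump) at 11022 ± 2335 CPM. The other 13 of the 20 highest genes were Ndufa4, Tnnc1, Ckm, Myl3, Mb, Cox6a2, Atp2a2, Atp5a1, mt-Cytb, Uqcrq, Aldoa, Uqcrc1 and Lpl.

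Gene lists fixed before the data were examined gave the level of each pathway. The 24 genes of the nuclear respiratory chain list together reached 104451 ± 1249 CPM, the 29 sarcomere and Z-disc genes 69277 ± 1250 CPM, the 25 fatty acid oxidation genes 38348 ± 769 CPM and the 20 calcium handling and excitation genes 23973 ± 3036 CPM. Glycolysis and glucose uptake reached 20776 ± 2327 CPM over 20 genes, led by Aldoa at 4609 ± 475 CPM and Ldhb at 3030 ± 165 CPM. Within that list Gapdh had only 15.9 ± 4.19 CPM, and this value is uncertain because its near-identical pseudogene copies held reads. Antioxidant and iron handling genes reached 16359 ± 681 CPM, led by Mb (myoglobin) and Fth1 (ferritin heavy chain, 3500 ± 14.2 CPM). The natriuretic and fetal-type stress list reached 5257 ± 332 CPM, with Nppa (atrial natriuretic peptide) the highest member at 2001 ± 496 CPM. Cardiac transcription and splicing factors were low, at 1336 ± 30.0 CPM over 21 genes, with Qk at 288 ± 6.90 CPM and Rbm24 at 201 ± 0.611 CPM. Circadian clock genes summed to 260 ± 11.7 CPM and the senescence and ageing-associated list to 634 ± 110 CPM. In the latter list Cdkn2a and Il6 had no reads and Cdkn1a had 20 and 13 reads.

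Markers of other cell types were present at lower levels than the cardiomyocyte list, which summed to 38172 ± 527 CPM. Erythroid genes summed to 7340 ± 486 CPM, led by Hba-a1 (alpha globin) at 4056 ± 252 CPM. Fibroblast and matrix genes summed to 4338 ± 698 CPM, of which Gsn alone held 3249 ± 515 CPM, and atrial cardiomyocyte genes to 3861 ± 785 CPM. Endothelial markers summed to 1124 ± 103 CPM, mural markers to 455 ± 27.3 CPM, macrophage and monocyte markers to 352 ± 27.5 CPM, and lymphocyte and antigen presentation markers to 306 ± 62.2 CPM. Adipocyte markers summed to 269 ± 138 CPM, with 366 CPM in replicate 1 and 171 CPM in replicate 2, and mesothelial markers to 50.6 ± 5.89 CPM. In the skeletal muscle list, Ckm, which heart also expresses, held nearly all of the 7553 ± 1411 CPM, and Myh1, Myh2, Myh4, Actn3 and Mylpf had no reads. The lung and thymus list had 1 read, on Cd8b1, and Schwann and neuron markers summed to 5.39 ± 0.584 CPM, with no reads on Mbp and Th. Among platelet and neutrophil genes Pf4 had 31 and 51 reads and S100a8, S100a9, Retnlg and Ngp had none. Cd3e, Cd8a, Slc4a1 and Lep also had no reads.

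The second question was how far the libraries differed. Gene levels correlated with Pearson r = 0.942 and Spearman rho = 0.924 on log2(CPM + 1) across 8836 genes with at least 10 reads in both together; genes are not independent replicates. By an exact two-sided binomial test with Benjamini-Hochberg adjustment, 297 of the 8836 genes (3.36%) differed, 120 higher and 177 lower in replicate 2, and 74 of them by more than 2-fold. With trimmed-mean (TMM) scaling 292 genes differed, 168 of them higher and 124 lower in replicate 2. The edgeR common dispersion was 0.0195, a coefficient of variation of 14.0% that holds technical spread as well. The synthetic ERCC spike-ins differed too. Of 27 tested against their own totals, 4 were called (14.8%, exact binomial test with Benjamini-Hochberg adjustment), each with at least 1522 reads per library and with log2 ratios from -0.23 to 0.25. These were ERCC-00074, ERCC-00096, ERCC-00002 and ERCC-00130, named after their values were seen. Of the 297 genes called, 39 had ratios no larger in size than the largest of these 4. They include Slc25a4, Myh6, Tpm1, Cox4i1, Ndufa4, Tnnc1, Mb and Ech1. Every spike-in with at least 1522 reads per library was called, while ERCC-00004, the next deepest with 644 and 1025 reads, was not. For genes this deep, a call with a ratio in that range may therefore be technical spread.

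**Figure D1:**
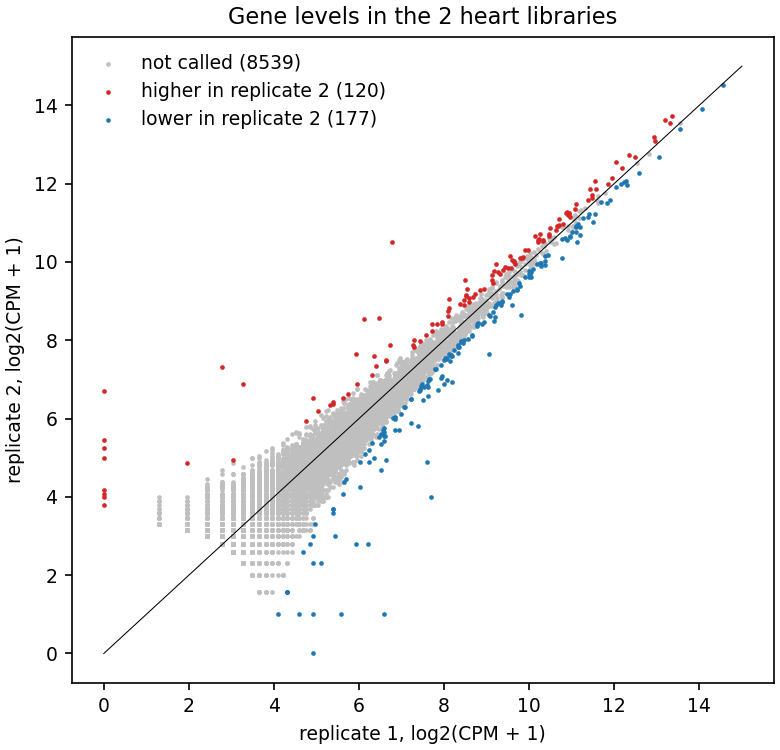
Levels of 8836 genes in replicate 1 (x axis) and replicate 2 (y axis), both as log2(CPM + 1), with 1 point per gene. Red points are the 120 genes higher and blue points the 177 genes lower in replicate 2 at an adjusted p under 0.05, and the line marks equal levels.

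Mitochondrially encoded genes were higher in replicate 2, and reads on the mitochondrial chromosome made up 1.08% of mouse reads in replicate 1 and 1.48% in replicate 2. Of 12 tested members 8 were called higher and none lower, and 9 were called higher when adjusted over the list alone. Their median log2 ratio of replicate 2 over replicate 1 was 0.56, at percentile 100 of 10000 random lists matched on mean CPM. The complex III subunit mt-Cytb had 4194 CPM in replicate 1 and 6046 CPM in replicate 2. Nuclear respiratory chain genes moved both ways, with 7 higher and 10 lower of 24 tested (8 and 10 adjusted over the list alone), and their median of 0.00 lay at percentile 62.7. Myh7, the beta myosin heavy chain of the sarcomere list (chromosome 14, 54970684 to 54994626), had 60 reads in replicate 1 and 381 in replicate 2, a log2 ratio of 2.11 (Benjamini-Hochberg adjusted p = 2.04e-32, exact binomial test). The ratio of Myh6 to Myh7 reads was 195 (151 to 256) in replicate 1 and 40.6 (36.7 to 45.1) in replicate 2; this pair was chosen after the values were seen. In the sarcomere list 8 genes were higher and 7 lower of 29 tested (8 and 10 adjusted over the list alone).

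Several lists were lower in replicate 2. In glycolysis and glucose uptake 7 of 19 tested genes were lower and none higher (11 and none adjusted over the list alone), with a median log2 ratio of -0.25 at percentile 0.235. Eno3, the muscle enolase, had a ratio of -0.49 and Pkm (pyruvate kinase) of -0.34. Gapdh entered the list with 18.9 CPM in replicate 1 and 12.9 CPM in replicate 2. With its near-identical copies it had 1797 and 1970 CPM, a change in the other direction. In the stress response list 5 of 16 genes were lower and none higher (6 adjusted over the list alone), with a median of -0.28 at percentile 1.88, and at 4.96 among lists matched on length too. The inducible heat shock genes Hspa1a and Hspa1b had 41 and 50 reads in replicate 1 and 6 reads each in replicate 2. Both lie outside the rule for named genes. Of the members it takes, Hspa8 had a log2 ratio of -0.61 and Hspb1 of -0.53, while Hspb6, Jund, Hspb7 and Dusp1 were not called. In the atrial list 3 of 7 genes were lower (5 adjusted over the list alone), namely Nppa at -0.51, Myl7 at -0.43 and Stard10 at -1.25, with a list median of -0.43 at percentile 0.16. In the adipocyte list 2 of 4 genes were lower (3 adjusted over the list alone). Car3 (carbonic anhydrase 3, chromosome 3, 14863512 to 14872523) had 132 and 29 reads and Cfd (adipsin) 29 and 7 reads, while Cidea, with 67 and 127 reads, was not called. The fibroblast list had 3 of 13 genes lower (4 adjusted over the list alone), Gsn, Sparc and Col3a1, and a median of -0.32 at percentile 1.91. The lymphocyte list had none of 4 called (1 lower adjusted over the list alone) and a median of -0.53 at percentile 2.28. With TMM scaling the fibroblast and lymphocyte medians lay at percentiles 2.56 and 2.68, and with known transcripts only at 11.0 and 7.07. Among lists matched on length too, the fibroblast median lay at percentile 8.73. Ckm, the only tested skeletal muscle gene, was lower at -0.38, also adjusted over the list alone.

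The natriuretic and fetal-type stress list held genes called in both directions. Myh7, Acta1 and Ankrd1 were higher and Nppa, Fhl2, Rcan1 and Ccn2 lower in replicate 2, with 3 and 4 called adjusted over the list alone as well. Its median of 0.24 lay at percentile 99.2, but with known transcripts only it was -0.45 at percentile 0.06. The median of 0.24 was the ratio of Fhl1, which had 30 and 52 reads and was not called. The summed level was 5492 CPM in replicate 1 and 5022 CPM in replicate 2, so the median marks no common shift. In fatty acid oxidation 4 genes were higher and 5 lower of 25 (5 and 5 adjusted over the list alone), with Fabp3 at 0.36, Pdk4 at 0.95, Ech1 at 0.17 and Acadvl at -0.34. Ppara had 0 and 17 reads, 3.89-fold against the 3 counts that 0 reads allow, with the counting error of the 17 left out. Calcium handling had 3 higher and 2 lower of 16 (3 and 2 adjusted over the list alone), with Pln at 0.44, Hrc at 0.52 and Casq2 at -0.33. Antioxidant and iron handling had 1 higher, Mb, and 1 lower, Gpx3, of 20 (4 and 1 adjusted over the list alone). The senescence list had 1 lower of 12, B2m (1 adjusted over the list alone). The cardiomyocyte list had 2 higher and 2 lower of 8 (2 and 3 adjusted over the list alone), and the endothelial list 1 higher of 13, Fabp4 (2 adjusted over the list alone). The erythroid list had 1 lower of 5, Hba-a1 (4 adjusted over the list alone), and globin counts are uncertain because of near-identical copies. No member was called, over all genes or adjusted over the list alone, among 11 clock genes, 20 cardiac transcription and splicing factors, 9 mural, 11 macrophage, 3 mesothelial and 1 platelet and neutrophil genes. The mural median of 0.28 lay at percentile 96.2, at 98.8 with known transcripts only and at 97.6 among lists matched on length too.

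**Figure D2:**
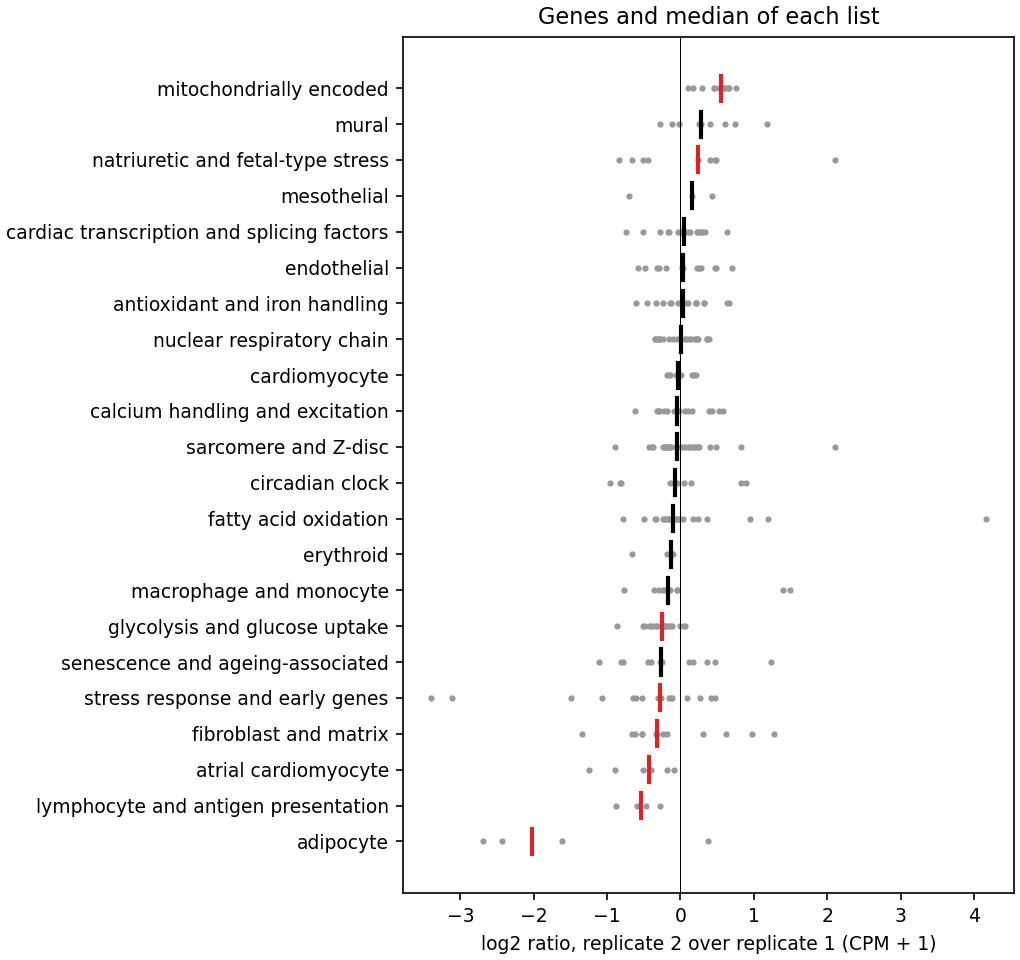
Log2 ratio of replicate 2 over replicate 1 on CPM + 1 (x axis) for the tested genes of 22 lists (rows), with grey points for genes and a bar for the list median. Red bars mark the 8 medians outside the central 95% of random lists, from the adipocyte list at -2.02 to the mitochondrially encoded list at 0.56. Ppara, with 0 and 17 reads, is drawn at 4.16 with the pseudocount.

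The largest differences in single genes involved several pseudogenes and overlapping gene names. Among genes with a mean of at least 50 CPM, the 5 lowest ratios in replicate 2 were those of Pnisr (-3.70), Car3 (-2.69), Irf2bp2 (-1.81), Hsp25-ps1 (-1.69) and H2-K1 (-1.59). The 5 highest were Coq3 (2.44), Oaz1-ps (6 and 117 reads), Gm15459 (3.73), Gm20427 (4.54) and Gm6055. The last had 0 and 104 reads, 23.8-fold against the 3 counts that 0 reads allow, with the counting error of the 104 left out. All 10 were called, and counts of overlapping names, of pseudogenes and of H2-K1, which has near-identical relatives, are uncertain. After gene names with overlapping exons on the same strand were pooled, 7 of these 10 lay within 2-fold, and Car3, Irf2bp2 and H2-K1 did not. Pnisr and Coq3 are 1 pooled locus and share 1 ratio (0.50, 0.25 to 0.76). The pooled intervals of Gm15459 (-0.70 to -0.49) and Gm20427 (0.16 to 0.77) also left out 0. That of Gm6055 (0.065 to 1.10) reached beyond 2-fold.

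The third question was how the reads divided between annotated and new transcript models. Known transcripts took 70.7 ± 2.09% of mouse reads (SD, n = 2), with 72.2% (72.1 to 72.3) in replicate 1 and 69.3% (69.2 to 69.4) in replicate 2. Incomplete splice matches, which hold only part of a known exon chain, took 13.3 ± 1.49%, with 12.2% (12.1 to 12.3) and 14.3% (14.2 to 14.4). New spliced models took 6.35 ± 0.322%, with 6.58% (6.52 to 6.64) and 6.12% (6.08 to 6.17), and these 2 shares differed by Fisher's exact test (two-sided, adjusted p = 1.31e-32 over 8 classes). The known and incomplete shares differed by more, with p too small to be represented. Genomic models took 5.91 ± 0.356%, antisense models 3.06 ± 0.463% and intergenic models 0.680 ± 0.0951%. Of the incomplete reads, 65.8% in replicate 1 and 58.6% in replicate 2 matched the 3' part of a known chain and 2.78% and 2.29% the 5' part. A further 30.8% (30.5 to 31.1) and 38.5% (38.3 to 38.8) were assigned to neither part, and 99.6% and 99.7% of these reads were on single-exon models.

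**Figure D3:**
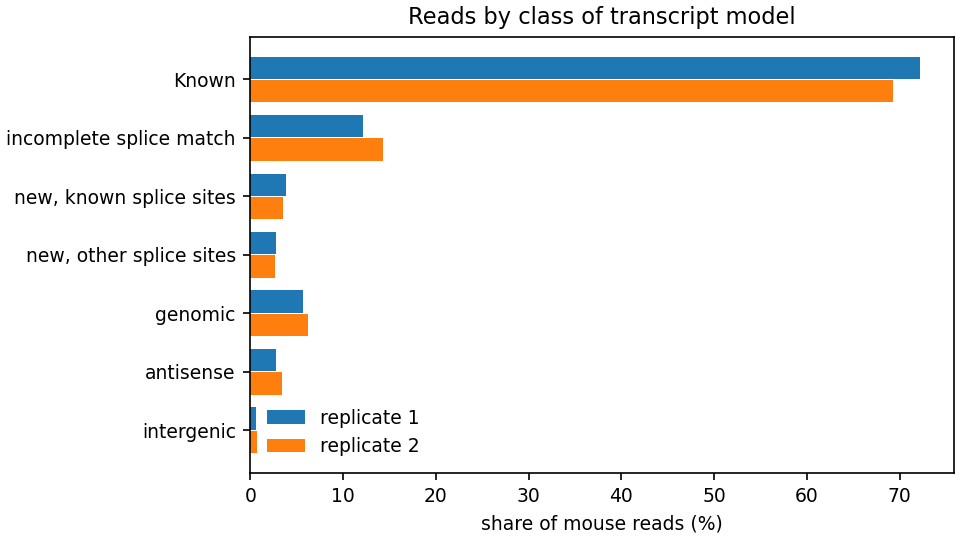
Share of mouse reads in percent (x axis) in each class of transcript model (rows), with 1 bar per library. Known transcripts hold 72.2% and 69.3% of reads and incomplete splice matches 12.2% and 14.3%.

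The incomplete share was larger for genes with longer transcripts. Across genes, the Spearman correlation between known transcript length and incomplete share was 0.284 over 3857 genes in replicate 1 and 0.276 over 4637 genes in replicate 2; genes are not independent replicates. In replicate 1 the median share was 1.49% for genes under 1000 nt and 12.8% for the 120 genes of 6000 nt or more. Known transcripts with at least 5 reads in one library were found in the other for 99.3 ± 0.753% of cases, and new spliced models for 96.9 ± 2.11%. At a minimum of 1 read in the first library these values were 80.2 ± 5.25% and 30.5 ± 5.29%.

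The new spliced transcripts with the most reads were compared by their share of the gene. Coordinates are in mm10. In Oaz1 (ornithine decarboxylase antizyme), a new 5-exon model on chromosome 10 from 80826682 to 80829284 held 96.4% of the gene's reads in each library. In Myh6, a new 39-exon model of 6603 nt on chromosome 14 from 54941367 to 54966574 held 13.2% (12.6 to 13.8) and 14.0% (13.4 to 14.5). A new model of Srl (sarcalumenin) held 65.5% and 65.2%, one of Mpc1 (mitochondrial pyruvate carrier) 96.4% and 94.0%, and one of Idh3b 80.6% and 79.1%. A second Myh6 model and models of Vdac3, Idh3g and Tmed2 were also among those with the most reads. Among new genes, the locus with the most reads lay on chromosome 17 from 39843013 to 39848035 on the minus strand, with 1033 and 1169 reads. It lay opposite Gm26917 and Gm42418 and overlapped AY036118 and a further annotated gene on its own strand. One locus opposite Klhl31 (chromosome 9, 77656669 to 77657908, minus strand) had 452 and 816 reads. The locus opposite Tmem250-ps (chromosome 2, 26136814 to 26138383, plus strand) had 433 and 783. The loci opposite Klhl31 and Tmem250-ps held single-exon models only, and whether their reads were given the wrong strand was not tested. A 3-exon locus between genes on chromosome 11 from 31545787 to 31549652 on the plus strand had 268 and 317.

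**Figure D4:**
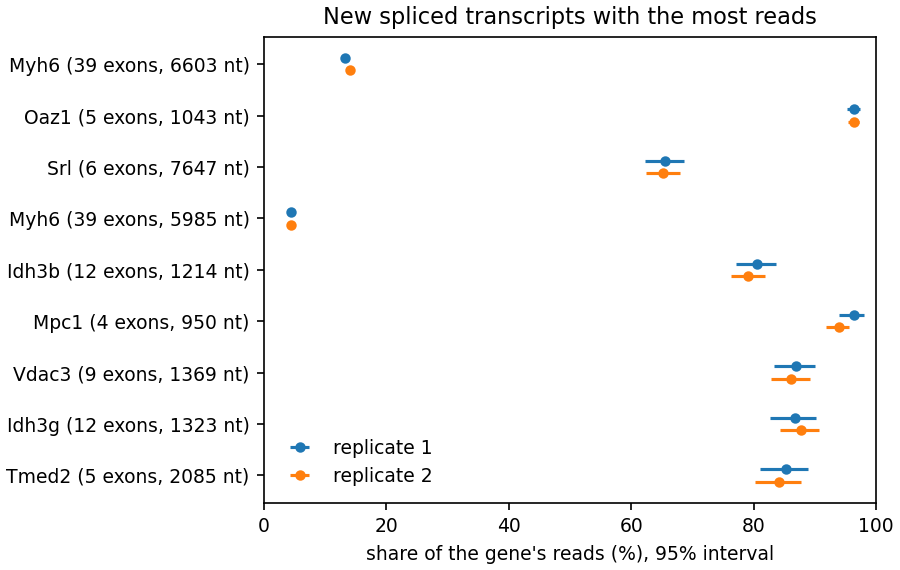
Share of the gene's reads in percent (x axis) held by 9 of the 10 new spliced transcripts with the most reads (rows), with 1 point per library and its 95% Clopper-Pearson interval. Shares range from 4.41% for the second Myh6 model to 96.4% for Oaz1.

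The fourth question was which isoforms cardiac genes used. Of 46 listed genes with at least 20 reads in each library, 1 differed in the share of its top transcript when adjusted over the list alone (Fisher's exact test, two-sided) and none when adjusted over all 3940 genes; the others showed no difference detectable at this depth. Without incomplete and genomic reads none differed. Tpm1-205 held 95.1 ± 0.222% of Tpm1 reads (SD, n = 2), Nppa-201 97.4 ± 0.0454% of Nppa reads, and Aldoa-201 92.5% and 91.5% of Aldoa reads. Pkm-202 held 84.3% and 84.9%, Slc25a3-206 81.5% and 79.2% and Atp2a2-202, a transcript of the sarcoplasmic calcium pump, 71.6% and 71.2%. These shares count all reads, incomplete and genomic ones included. Use was more divided in Ndufs1, where Ndufs1-201 held 58.1% and 57.9%, and in Gnas, where Gnas-207 held 37.2% and 37.7%. In Trdn the single-exon transcript Trdn-204 held 33.8% and 34.0%, and 53.8% and 58.6% without incomplete and genomic reads. Ldb3-203 held 50.2% and 44.9% of Ldb3 reads, but 90.1% and 86.7% without incomplete and genomic reads. The top transcript of Tnni3 (cardiac troponin I) was a new model with 30.9% and 26.0%. That of Tnnt2 (cardiac troponin T) was an incomplete model with 26.4% and 25.3%, and that of Lmna an incomplete model with 33.9% and 46.1% (adjusted over the list alone, p = 0.0606, Fisher's exact test). In Pde4dip it was a genomic model with 9.78% and 10.7%. New spliced models were also the top transcript in Camk2d, Pdlim5, Mbnl2, Itgb1, Ktn1, Mef2a and Nebl, all named because they share this feature, a choice made after the values were seen. Over the 46 genes the median share of the top transcript was 47.5 ± 2.02% (SD, n = 2) with all reads counted. With shares first averaged over the libraries the median was 48.3%. It was 63.1% over the 36 genes tested without incomplete and genomic reads.

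Across all 3940 genes with at least 2 transcripts and 20 reads in each library, 33 differed in the share of the top transcript. The 5 with the smallest adjusted p were Atp5b, Slc25a4, Coq3, Des and Slc25a5. The Coq3 model was an incomplete single-exon model with 0 and 319 reads. Because Coq3 and Pnisr form 1 pooled locus, this difference may come from the names given to reads and not from isoform use. In Atp5b an incomplete 2-exon model held 46.4% of reads in replicate 1 and 58.0% in replicate 2, and in Des (desmin) the known transcript Des-201 held 78.7% and 69.5%. Without incomplete and genomic reads, 2 genes differed, both at an adjusted p of 0.0274 (Fisher's exact test). They were Cox4i1, where Cox4i1-204 held 65.9% and 69.0%, and Tsc22d3, where Tsc22d3-201 held 64.3% and 36.9%. Cox4i1-204 is a known 3-exon transcript of 578 nt that starts at 120672590, inside the gene (chromosome 8, 120668222 to 120674207, plus strand). Whether reads cut short at the 5' end were counted in it was not tested, and leaving out incomplete reads would not remove them. In the ERCC spike-ins, which are synthetic and unspliced, 0.722% (0.570 to 0.901) of reads in replicate 1 and 0.582% (0.470 to 0.713) in replicate 2 lay outside the known class. Nearly all of these were antisense (76 of 77 and 93 of 93 reads), with 1 and 0 spliced reads, so these shares give no error rate for new spliced transcripts in mouse genes.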

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

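Chosen after the result was seen were the tests of different gene names for Pnisr, Coq3 and Gm15459 and for Car3, Irf2bp2 and H2-K1, of tissue makeup and a common factor, of near-identical copies, whose search was changed after its first results, and of length in Gapdh and at fixed length in ribosomal protein genes. No biological explanation was tested, since the design holds 1 group.

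Reads on new intergenic genes, which the gene comparison leaves out, numbered 4451 in replicate 1 and 7911 in replicate 2. Of these, 4222 and 7504 were on models of the intergenic class and the others on models of other classes in the same genes. These genes are listed because they have reads, so no background level was tested.

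Many of the largest single-gene differences may come from 1 locus being given different gene names in each library. After overlapping names were pooled, with Pnisr and Coq3 as 1 locus, the largest of the log2 ratios of Pnisr, Coq3 and Gm15459 was 0.595 in size. Of the other 7 named genes, 4 lay within 2-fold. For Car3, Irf2bp2 and H2-K1 no other name overlapped, so pooling changed nothing (smallest ratio 1.59 in size) and tests nothing there. Different transcript ends would leave known reads within 2-fold, which held for 2 of the 10 genes: Coq3, where this stays open, and Gm20427, which had no known reads and decides nothing. Pnisr was outside 2-fold with only 2 and 7 known reads, in the direction opposite to its gene ratio, and decides nothing either. What set Car3, Irf2bp2 and H2-K1 apart stays open.

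Lists shifted between the libraries were set against random lists matched on transcript length as well as mean CPM. The glycolysis (percentile 1.09), mitochondrially encoded (100), atrial (0.03), lymphocyte (1.17) and adipocyte (0.0) medians stayed outside the central 95%, which argues against length as the whole explanation. The natriuretic median (99.4) also stayed outside, but genes of that list were called in both directions, so it marks no common shift. The stress response (4.96) and fibroblast (8.73) medians went inside, and the mural median, inside by mean CPM, went outside (97.6). These lists also used coarser CPM bins and, for fibroblast, 12 of 13 genes. Such moves therefore cannot be put down to length alone. Across 8370 genes the Spearman correlation of log2 ratio with length was -0.056. Less of 1 tissue in replicate 2 would lower all its markers by 1 factor; the markers differed by more than counting noise in the adipocyte (permutation p = 1.00e-05) and atrial (permutation p = 4.00e-05) lists, but those tests leave out the spread between libraries and exclude nothing. With the edgeR dispersion allowed for, a fraction of 0.265 of simulated lists with 1 common factor was as unequal as the atrial list, so less atrial tissue stays open, while for the adipocyte list that fraction was at most 1.00e-05, the smallest that the simulations can give, which argues against 1 common factor there but leaves tissue makeup open if other cells also express Cidea, the only tested marker with a ratio above 0. Differences between the samples in origin, handling or RNA quality stay open and untested, and the incomplete share also differed (12.2% and 14.3%).

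Gapdh had few reads beside other glycolysis genes, and a candidate explanation is that reads went to near-identical copies. Across 79 ribosomal protein genes, mean CPM was lower with more copies (Spearman rho = -0.397, permutation p = 0.00034). Length alone gave rho = -0.105 (permutation p = 0.354), which as a missed threshold excludes nothing, but the relation with copies stayed at fixed length (partial rho = -0.393, permutation p = 0.00046), and 6 glycolysis genes within 25% of the length of Gapdh had at least 134 CPM against its 15.9, which argues against length as the whole explanation. Gapdh and its 162 copies together had 1884 CPM, above the lowest quartile of 238 CPM of the other glycolysis genes, mostly on the pseudogenes Gm12671, Gm12033, Gm7336 and Gm5559, and whether those are themselves expressed cannot be read from counts. In 2 earlier searches with minimap2, which used a retained-intron transcript of Gapdh, 0 and 2 copies were found and the sum stayed at 15.9 CPM, below that quartile; with the coding transcript minimap2 found 111 copies and also gave 1884 CPM, so the transcript searched decided the outcome.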

How the results depend on the processing

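The alternatives that pooled gene names, left out models under 10 nt, pseudogenes or single-exon models, or matched lists on length were chosen after seeing the data. The count of genes differing stayed between 214 and 338 under 10 alternatives, and the count of shifted lists between 6 and 8, though not always the same lists: with known transcripts only the natriuretic median went from 0.24 to -0.45. Isoform calls numbered 30 with at least 10 reads, 39 with at least 50 and 31 by permutation, against 33. The share of gene calls higher in replicate 2 was 40.4%, and 57.5% with TMM or 57.0% with DESeq2 scaling. The correlation was 0.930 with a pseudocount of 0.1 CPM and 0.959 with 5 CPM, and 0.930 with no filter and 0.958 with at least 50 reads. In multi-exon transcripts the known, incomplete and new spliced shares were 81.5%, 10.5% and 7.73%. Transcripts with at least 5 reads gave 76.9% known and 3.66% new spliced, and leaving out the 10 highest genes gave 11.3% incomplete and 6.74% new spliced. Leaving out 1 replicate gave 69.3% to 72.2% known, 12.2% to 14.3% incomplete, 6.12% to 6.58% new spliced, 0.582% to 0.722% of spike-in reads outside the known class and a length correlation of 0.276 to 0.284. That correlation was 0.300 with at least 50 reads, 0.345 with at least 100 and 0.274 with the longest transcript. Recovery of known transcripts was 93.1% from 2 reads, 97.8% with 2 and 87.9% with 5 reads in the other library. Recovery of new spliced models was 72.8% from 2 reads and 99.6% from 10, and 91.3% with 2 and 69.7% with 5 reads in the other library. Without incomplete and genomic reads the cardiac isoform genes gave 0 calls by Fisher's exact test (2 genes over all 3166 tested), and 4 genes were called without single-exon models. The cause of these shifts was not tested, except that higher read minimums leave fewer models. Recovery, gene differences and isoform differences need both libraries, so leaving one out gave no value. No paired analysis was possible because there is 1 group. At this depth, about 60.1% of models in each library had 1 read.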
